A study of Mus musculus with 30 samples.

How the data were processed

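Chromatin immunoprecipitation followed by sequencing was applied to NOS1+ N1E115 cells, a mouse neuroblastoma line, kept for 3 days at 4% or 20% O2, per the labels. The series holds 30 samples. Of these, 24 are immunoprecipitated libraries, with 2 libraries per O2 level for each of 6 antibodies, and 6 are inputs, which are not analysed here. The antibodies recognised the insulator protein CTCF, the cohesin subunit RAD21, histone H3 acetylated at lysine 9 (H3K9ac), RNA polymerase II (POLR2) and its forms phosphorylated at serine 5 (POLR2S5) or serine 2 (POLR2S2) of the carboxy-terminal repeats. Groups and replicate numbers came from the labels. The header of the CTCF list of 20% O2 replicate 1 carries the code Nm21, which the labels do not explain, so that library was placed by its label alone. Nothing in the labels says that the 2 libraries of a group came from separate cultures. P-values of tests between libraries therefore measure the spread between these libraries, which may be technical. Fisher's exact test takes genes or regions as units and the sign-flip test takes antibodies. The list test camera sets the regions of a list against other regions. None of these measures the spread between cultures.

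The build mm10 and the tools BWA, Picard, SICER and, for the later samples, MACS2 are named per the submitters' processing notes; their versions and settings are not given in the sources used here. Peaks were called with MACS2 for CTCF, RAD21 and H3K9ac and with SICER for the polymerase forms, per the file headers. Each list belongs to 1 library, set against an input of the same O2 level, as the names of the deposited lists state. The last column of the deposited MACS2 lists was read as −log10 of a q-value, judged from its values, since the column has no name. The last column of the deposited SICER lists was read as a whole-number count of reads per island, not scaled to library size, on the same grounds. These scores are the authors' own. The MACS2 scores served only to rank or filter peaks within a list. The SICER counts served for that too, and were also summed over regions and compared between libraries. The sum of reads over islands is not the depth of a library; the depth is not given in the sources used here, and no counting interval was computed.

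For replicate 2, the deposited list under its own label held either peak summits or a copy of a second list placed with replicate 1. In all 12 cases the scores were equal and every summit lay inside its peak, so the pair was counted once, as replicate 2. Replicates 1 and 2 of a group shared at most 0.83% of their intervals exactly and were kept as separate samples.

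Replicates 1 and 2 of every antibody were sequenced on different flow cells, with 3 flow cells in all, per the file headers. The replicate number therefore marks a sequencing round that holds both O2 levels. Deviations of same-numbered libraries from their group means correlated at 0.53 for POLR2, 0.55 for POLR2S5 and 0.39 for POLR2S2, across regions, which are not independent replicates. Values within rounds, or with the replicate number as a block, are given beside the pooled values of list length, similarity and the gene lists described singly.

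Chromosomes 1 to 19, X and Y were used. Peaks of the 4 libraries of an antibody were merged into regions where they overlapped by at least 1 bp. A region was called specific to an O2 level when both libraries of that level and neither of the other had a peak in it. The same count was made for the other splits of the 4 libraries into pairs, by round and crossed; with 3 splits no share under 0.05 is possible. A total of 21887 protein-coding genes came from the RefSeq gene table of GRCm38.p6, the same build as mm10. That table gives no strand, so the promoter window fixed before the data were examined was replaced by windows of 1 kb to each side of both annotated gene ends. A "gene end" is therefore the start or the end of a gene. Peak centres were placed at gene ends, inside genes or outside genes; exons and introns were not told apart.

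Similarity of a pair of lists was the Jaccard index in base pairs, tested over the 6 antibodies with an exact sign-flip permutation test (two-sided, smallest p 0.031). Values per library were compared with an exact permutation test of 2 against 2 libraries (two-sided, smallest p 0.333, so that no such comparison can pass 0.05). Gene lists were tested among O2-specific gene ends with a two-sided Fisher's exact test against genes called in at least 1 of the 4 libraries, with Benjamini-Hochberg adjustment over 274 tests. Scores at regions called in all 4 libraries were ranked within each library over those regions alone. The median rank difference of a list, 4% minus 20% O2 in percentile points, was placed among 10000 random lists matched on mean rank, as a description with no test across libraries.

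Reads in the islands of each region called in all 4 libraries were summed and compared with edgeR's quasi-likelihood test (version 4.0.16, TMM scaling, Benjamini-Hochberg adjustment, threshold 0.05), on 7811 regions for POLR2, 9933 for POLR2S5 and 5936 for POLR2S2. Log2 ratios are 4% over 20% O2. Alternatives were the replicate block, DESeq2 (version 1.42.0), a low-count filter, reads per kb of island and each library left out in turn. Gene lists with enough shared regions were tested with camera of limma (version 3.58.1), with its preset correlation and with an estimated one, adjusted within each antibody, and placed among 10000 random lists matched on read level. Other alternatives kept the better scoring 50% of each list, shortened all lists of an antibody to equal length, required 50% overlap, merged regions within 1 kb, used all contigs, widened windows to 2.5 kb or used whole genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

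The gene lists were fixed before the data were examined, as were the tests and alternatives other than those named at the end of this paragraph. They cover HIF (hypoxia-inducible factor) targets and glycolysis, hypoxia signalling factors, nitric oxide signalling, neuroblast and sympathetic identity, neuronal structure and synapse, oxidative phosphorylation, the oxidative stress response, the unfolded protein response, immediate early genes, the cell cycle, cholesterol synthesis, apoptosis and p53, histone demethylases and chromatin enzymes, CTCF and cohesin subunits, RNA polymerase II and its cofactors, ribosomal proteins, protocadherin clusters, imprinted genes, and markers of astrocytes, oligodendrocytes and Schwann cells, macrophages and microglia, fibroblasts and endothelium. All names matched the gene table except 4 of the imprinted genes. Genes were named by a fixed rule: Nos1; up to 10 genes per antibody and direction with O2-specific ends, by mean percentile of score within the lists; genes specific in the same direction for several antibodies; specific members of the gene lists; and leading specific regions away from gene ends. Regions named for their reads or their rank were chosen after their values were seen. Chosen after seeing the data were also the gene-end windows, camera and the random lists for reads, reads per kb, random lists drawn from gene ends, similarity across rounds, genes on the same peaks counted once, the histone genes, and the tests of list length, island number, separate rounds, neighbouring genes and the interval of the H3K9ac share.

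Region calling was tested on simulated lists and found every planted region for each antibody, such as 2117 of 2117 planted at 4% O2 for CTCF. The simulated sites stood apart, kept their width and were shifted little. The test therefore checks the script and not the calls in real lists, whose peaks differ in width and threshold. The read test was tested on simulated counts with 100 regions changed 2-fold and 100 changed 4-fold per antibody. Without the block it recovered 0% of both sizes for POLR2, POLR2S5 and POLR2S2. With the replicate block it recovered 37% of the 2-fold and 100% of the 4-fold changes for POLR2, 20% and 94% for POLR2S5, and 6% and 63% for POLR2S2, with 10, 7 and 2 false calls. A genome sequence was not used here, so the CTCF motif was not searched.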

Results

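The series addressed how culture at low oxygen relates to genomic binding of CTCF, RAD21, H3K9ac and RNA polymerase II in N1E115 mouse neuroblastoma cells. Each of 6 antibodies was used on 2 libraries at 4% O2 and 2 at 20% O2. Replicates 1 and 2 are called rounds 1 and 2 below, after their sequencing. Coordinates are mm10.

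CTCF lists held 124797 and 81759 peaks at 4% O2 and 126873 and 73200 at 20% O2, in rounds 1 and 2. RAD21 lists held 39012 and 71225 peaks against 26908 and 73328, and H3K9ac lists 79516 and 92649 against 71857 and 84395. Islands numbered 19918 and 18494 against 11172 and 23262 for POLR2, 24635 and 20686 against 23060 and 24164 for POLR2S5, and 18938 and 16174 against 17765 and 17480 for POLR2S2. H3K9ac lists were longer at 4% O2 in both rounds, by ratios of 1.11 and 1.1 (exact permutation p = 0.667, n = 2 per level). For the other 5 antibodies the ratios of the rounds lay on opposite sides of 1, with exact permutation p = 1.0 for each.

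POLR2S2, the elongating form, was the polymerase form with more island reads at 4% O2 in both rounds and in both pairings of libraries. Its islands held 10.43 and 16.6 M (mega) reads at 4% O2 and 4.87 and 9.7 M at 20% O2 (13.52 ± 4.36 against 7.28 ± 3.42 M, SD, n = 2, exact permutation p = 0.333). The ratio was 2.14 in round 1 and 1.71 in round 2, and the islands covered 236.7 and 267.0 Mb against 151.8 and 256.9 Mb. POLR2 islands held 5.93 and 10.17 against 2.06 and 8.6 M reads over 135.3 and 183.4 against 59.5 and 174.5 Mb. POLR2S5 islands held 10.98 and 12.01 against 5.93 and 12.37 M reads over 214.4 and 241.6 against 154.2 and 258.0 Mb. The 20% O2 library of round 1 had the fewest island reads for each polymerase form.

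**Figure D1:**
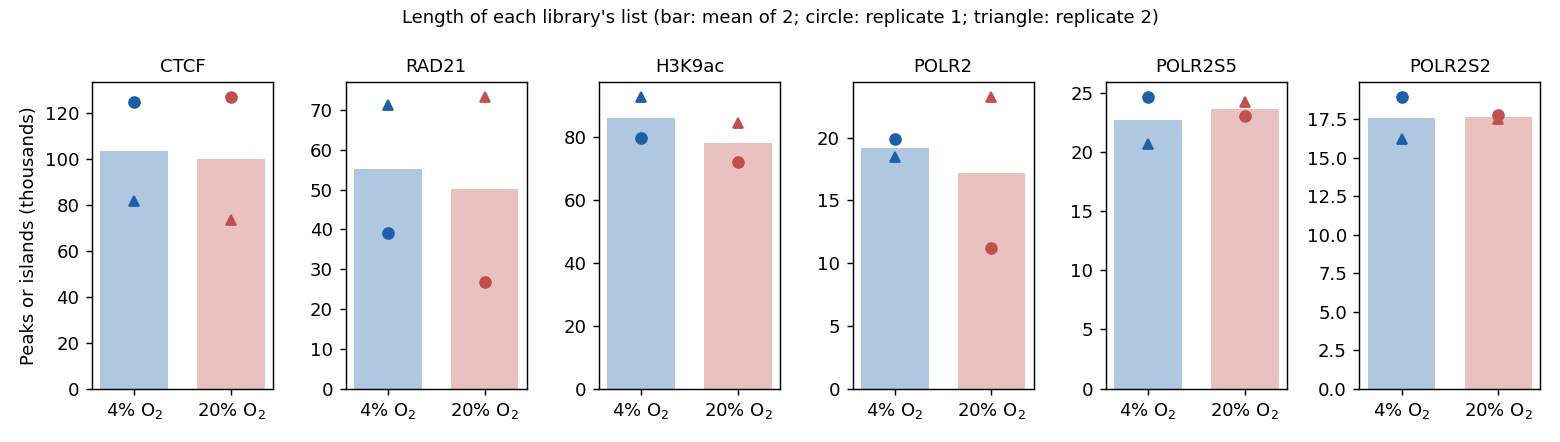
Number of peaks or islands divided by 1000 (vertical axis) at 4% and 20% O2 for each antibody; bars are means of 2 libraries, circles replicate 1 and triangles replicate 2. Replicates lie far apart for CTCF (124797 and 81759 peaks at 4% O2) and RAD21 (26908 and 73328 at 20% O2).

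Averaged over antibodies and pairs, lists resembled each other by round more than by O2 level. The mean Jaccard index was 0.49 for libraries of the same O2 level and 0.517 for libraries of different levels, a difference of -0.028 ± 0.03 (SD over 6 antibodies, exact sign-flip permutation p = 0.125). With pairs of different O2 level taken within rounds only, the replicate block, the difference was -0.071 ± 0.047 (exact permutation p = 0.031). With both kinds of pair taken across rounds, chosen after seeing the data, it turned to 0.015 ± 0.014 and lay above 0 for 6 of 6 antibodies (exact permutation p = 0.031). The antibodies were sequenced in the same rounds, so they are not independent units in these permutation tests. POLR2S2 had the largest of these differences, 0.041, and RAD21 the smallest, 0.001. For the polymerase forms the order by round did not hold in round 1. There the 4% and 20% O2 libraries had indices of 0.335, 0.512 and 0.501 for POLR2, POLR2S5 and POLR2S2. The 4% O2 libraries of both rounds had 0.548, 0.63 and 0.665. In round 2 the 4% and 20% O2 libraries had 0.59, 0.659 and 0.642.

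HIF targets and glycolysis genes carried more polymerase at 4% O2 as a list. The median log2 ratio of their regions was 0.35 over 40 regions for POLR2, 0.47 over 48 for POLR2S5 and 0.58 over 36 for POLR2S2. In rounds 1 and 2 the medians were 0.26 and 0.44, 0.38 and 0.46, and 0.56 and 0.71. The ratio was above 0 in both rounds for 28, 32 and 28 of these regions and below 0 in both for 3, 5 and 1. Camera gave adjusted p = 1.1e-06, 3.8e-09 and 1.5e-10, against adjusted p = 0.79, 0.84 and 0.95 with an estimated correlation. No region of the list passed edgeR, whether adjusted over all regions or adjusted over the list alone. In simulated counts the test without the block, adjusted over all regions, recovered 0% of planted changes. The lack of such calls without the block therefore carries no weight, here and for the lists below. With the replicate block 7, 5 and 16 passed adjusted over the list alone, and 0, 0 and 1 over all regions. Scaling to reads per kb of island moved the median of all shared regions to -0.48, -0.30 and -0.37. On that scale the list medians fell to -0.05 for POLR2S5 and 0.12 for POLR2S2, at the 99.97 and 100 percentiles of random lists. For POLR2 the list median of -0.48 equalled that of all regions and the difference was lost, at percentile 6.55.

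Slc2a1, a glucose transporter, had a POLR2S5 log2 ratio of 2.22 ± 0.44 (SE, n = 2 per level) over chromosome 4, 119100801 to 119142000, and a POLR2 ratio of 1.75 ± 0.55. Its POLR2S5 reads were 1245 and 2551 at 4% O2 and 176 and 515 at 20% O2, on islands of 38.2 and 41.2 kb against 3.6 and 10.8 kb, and per kb the ratio was -0.52. Hk2, a hexokinase, had a POLR2S2 ratio of 2.54 ± 0.64 over chromosome 6, 82720201 to 82776400, and -0.18 per kb. P4ha1, a subunit of collagen prolyl hydroxylase, had 1.74 ± 0.48 in POLR2S2 over chromosome 10, 59319001 to 59382000, and 1.2 per kb. Its reads were 5536 and 11971 against 558 and 2582. P4ha1 was the list member that passed edgeR over all regions with the replicate block (1.85 ± 0.26, adjusted p = 0.0488), while its adjusted p without the block was 0.809. The region of Bnip3, a mitophagy receptor, had 2.13 ± 0.72 in POLR2, 1.16 ± 0.31 in POLR2S5 and 1.44 ± 0.32 in POLR2S2; it also spans Ppp2r2d. Regions of the glycolytic enzymes Pfkl, Pgk1 and Ldha had POLR2S2 ratios of 1.44 ± 0.33, 1.32 ± 0.37 and 1.02 ± 0.28. Vegfa, an angiogenic growth factor, had -0.02 ± 0.36 in POLR2S2, and Stc2, a secreted glycoprotein, had -0.66 ± 0.34, -0.96 ± 0.40 and -1.32 ± 0.46 in POLR2, POLR2S5 and POLR2S2.

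**Figure D2:**
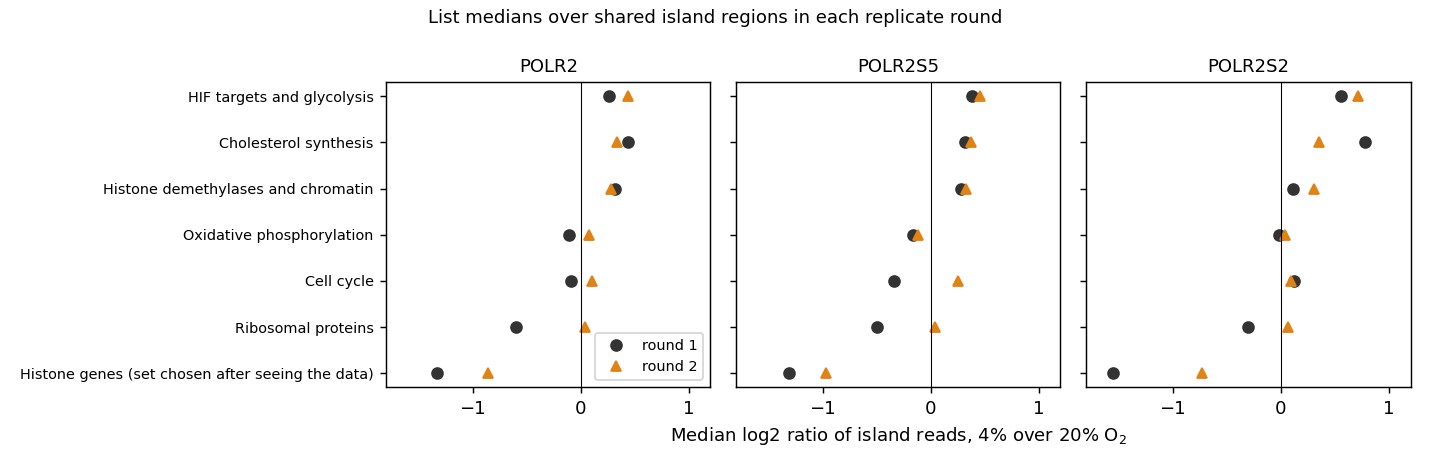
Median log2 ratio of island reads, 4% over 20% O2 (horizontal axis), of gene lists over regions called in all 4 libraries, for each polymerase form; circles are round 1 and triangles round 2. HIF targets lie above 0 in both rounds (0.26 and 0.44 for POLR2, where the difference from other regions was lost in reads per kb of island), and histone genes, a set chosen after seeing the data, lie below 0 (-1.33 and -0.86 for POLR2).

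H3K9ac ranked higher at the same list at 4% O2. Its 76 gene-end regions had a median rank difference of 8.74 percentile points, 7.9 and 4.31 in the rounds, above 100% of random lists, with 37 regions higher and 10 lower in both rounds. A Bnip3 region on chromosome 7, 138909646 to 138911879, ranked at 84.1 and 75.9 at 4% O2 and at 27.7 and 50.9 at 20% O2. One at Egln3, a prolyl hydroxylase that marks HIF for degradation, on chromosome 12, 54203998 to 54205337, ranked at 65.6 and 78.3 against 19.8 and 58.2. One at Pdk1, a kinase that inhibits pyruvate dehydrogenase, on chromosome 2, 71873320 to 71874809, ranked at 52.6 and 78.2 against 8.8 and 63.0. At Eno1, a glycolytic enzyme, a region on chromosome 4, 150236050 to 150237080, ranked lower at 4% O2, at 53.3 and 73.0 against 76.1 and 92.5. Rank differences of the polymerase forms at this list were 4.65, 6.94 and 11.49 points for POLR2, POLR2S5 and POLR2S2, at percentiles 99.97, 100 and 100.

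Cholesterol synthesis genes had median log2 ratios of 0.54 over 12 regions for POLR2, 0.33 over 18 for POLR2S5 and 0.50 over 18 for POLR2S2, above 0 in both rounds for 8, 14 and 14 regions. In rounds 1 and 2 the medians were 0.44 and 0.34, 0.32 and 0.37, and 0.78 and 0.35. Dhcr7, which makes the last step to cholesterol, had 1.44 ± 1.05 in POLR2S2 over chromosome 7, 143829001 to 143849600, and Lss, which makes lanosterol, had 0.93 ± 0.62 over chromosome 10, 76527001 to 76561800. In H3K9ac, 36 regions of the list ranked 10.43 points higher at 4% O2 (18.76 and 2.51 in the rounds, percentile 99.97). A region at Hmgcs1, an early enzyme of the pathway, on chromosome 13, 119688908 to 119690015, ranked at 91.5 and 82.7 against 37.9 and 33.7. Camera gave adjusted p = 0.033, 0.014 and 0.065, and with the replicate block 0.0084, 0.0076 and 0.0082. With an estimated correlation the adjusted p = 0.79, 0.84 and 0.96. No region of the list passed edgeR, over all regions or adjusted over the list alone, with or without the block. Per kb the list lay at percentile 49.72 for POLR2, so its direction was lost there, and at 99.98 and 100 for POLR2S5 and POLR2S2.

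Histone demethylases and chromatin enzymes had medians of 0.27 over 28 regions, 0.30 over 39 and 0.25 over 30 for POLR2, POLR2S5 and POLR2S2. Kdm3a and Kdm4b belong to this list and to that of HIF targets, so the lists are not fully separate. In rounds 1 and 2 these were 0.32 and 0.28, 0.28 and 0.33, and 0.11 and 0.31. Tet2, which oxidises methylated cytosine, had 1.84 ± 0.67 in POLR2S5 over chromosome 3, 133494401 to 133528200. Kdm2a, a histone demethylase, had 1.11 ± 0.33 in POLR2S5 over chromosome 19, 4311601 to 4353000. The region of Ezh2, a histone methyltransferase, and Cul1 had -1.64 ± 0.56 in POLR2S2 over chromosome 6, 47484401 to 47537800. Camera gave adjusted p = 0.021, 0.0017 and 0.24, and adjusted p = 0.79, 0.84 and 0.96 with an estimated correlation. Adjusted over the list alone, 0 regions passed edgeR, and 0, 1 and 3 with the replicate block; over all regions none passed either way. Per kb the difference from other regions was lost for all 3 forms, at percentiles 22.36, 79.75 and 96.73, inside the middle 95% of random lists.

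Ribosomal protein genes had medians of -0.35, -0.25 and -0.15 over 29 regions each. In round 1 these were -0.60, -0.50 and -0.30 and in round 2 0.04, 0.04 and 0.07, so the direction of reads did not hold in both rounds (camera adjusted p = 0.13, 0.13 and 0.56). Among random lists the medians lay at percentiles 0, 0.04 and 5.46, and per kb at 0.67, 0.01 and 0.04. Within rounds the percentiles were 0, 0 and 1.49 in round 1 and 17.92, 16.8 and 53.87 in round 2. In H3K9ac the list ranked at -3.52 points over 58 regions, -2.18 and -6.86 in the rounds, percentile 1.29 of random lists. Rank differences of POLR2, POLR2S5 and POLR2S2 were -6.14, -3.15 and -4.92 points, at percentiles 0, 0.2 and 1.97. In rounds 1 and 2 they were -8.91 and -3.08, -6.66 and -0.8, and -7.63 and 0.51. By rank the direction thus held in both rounds for POLR2 and POLR2S5, but not for POLR2S2.

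No other fixed list passed camera. Medians for POLR2, POLR2S5 and POLR2S2 were 0.28, 0.14 and 0.25 for nitric oxide signalling (adjusted p = 0.085, 0.55 and 0.56) and -0.22, -0.12 and -0.28 for neuroblast and sympathetic identity (0.90, 0.55 and 0.19). In the latter list Hand2, a transcription factor of sympathetic neurons, had -0.91 ± 0.58, -0.91 ± 0.67 and -0.98 ± 0.60, and Th, the first enzyme of catecholamine synthesis, 0.74 ± 0.46, 0.52 ± 0.27 and 0.38 ± 0.28. Hypoxia signalling factors had -0.04, 0.16 and 0.32 (0.91, 0.47 and 0.56), and neuronal structure and synapse 0.09, 0.03 and 0.15 (0.49, 0.97 and 0.72). Oxidative phosphorylation had 0, -0.13 and -0.01 (0.91, 0.56 and 0.95), and the oxidative stress response -0.08, -0.08 and -0.04 (0.91, 0.57 and 0.95). The unfolded protein response had -0.09, -0.10 and -0.02 (0.84, 0.085 and 0.56). Immediate early genes had -0.04, 0.01 and 0.07 (0.98, 0.55 and 0.95), and the cell cycle 0.05, -0.04 and 0.07 (0.98, 0.59 and 0.95). Apoptosis and p53 had 0.15, 0.09 and 0.21 (0.84, 0.59 and 0.56), and CTCF and cohesin subunits -0.02, -0.07 and 0.01 (0.98, 0.56 and 0.95). RNA polymerase II and cofactors had 0.07, 0.02 and 0.06 (0.24, 0.62 and 0.72), and imprinted genes -0.24, -0.26 and -0.27 (0.43, 0.47 and 0.56). Rounds differed in sign for several of these medians, such as -0.34 and 0.25 for the cell cycle and -0.32 and 0.06 for the unfolded protein response in POLR2S5. In these lists 1 region passed edgeR adjusted over the list alone, among the unfolded protein response regions of POLR2S5 (Atf6, a stress sensor, chromosome 1, 170715401 to 170872600, -2.48 ± 0.45, and 0.65 per kb). With the replicate block the list-alone counts for POLR2, POLR2S5 and POLR2S2 were 0, 3 and 1 for the unfolded protein response, 0, 1 and 2 for neuronal structure, 0, 0 and 2 for neuroblast identity, and 1, 1 and 0 for apoptosis. They were 1, 0 and 0 for imprinted genes, 0, 1 and 0 for oxidative phosphorylation, and 0, 0 and 1 for hypoxia signalling factors. Over all regions none passed, with or without the block.

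CTCF ranked higher at 4% O2 at regions at gene ends in general, by a median of 3.25 points, as did RAD21, by 4.31 points. Ribosomal protein genes had a CTCF rank difference of 7.16 points over 29 regions, 3.56 and 8.41 in the rounds, at percentile 98.3 among random lists of gene-end regions. Oxidative phosphorylation genes had a RAD21 rank difference of 17.67 points over 6 regions, 33.33 and 15.16 in the rounds, at percentile 99.23 of such lists. HIF targets had a CTCF difference of 4.48 points over 40 regions, and cholesterol synthesis genes 9.05 over 10. For POLR2S2, nitric oxide signalling genes ranked 11.19 points higher at 4% O2 over 13 regions, 11.16 and 0.26 in the rounds, at percentile 99.5 of random lists. Neuroblast and sympathetic identity genes had -2.65 points in POLR2S5 and -5.4 in POLR2S2, at percentiles 2.23 and 3.08.

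H3K9ac was called at the ends of 11532, 12309, 11718 and 12222 of 21887 genes (4% O2 rounds 1 and 2, then 20% O2), and markers of other cell types were called to varying extents. Of 9 endothelial markers at most 2 had a call in any library. For H3K9ac, 3, 4, 3 and 4 of 12 macrophage and microglia markers and 3, 4, 3 and 4 of 11 fibroblast markers were called, in the same order. Astrocyte markers were called at 3, 3, 4 and 4 of 9 genes, and Aldoc among them is also a glycolysis gene. Oligodendrocyte and Schwann cell markers were called at 4, 5, 6 and 5 of 11, with a POLR2S5 median log2 ratio of -0.20 over 9 regions and a POLR2S2 median of -0.12 over 7 (camera adjusted p = 0.55 and 0.86).

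Single regions did not pass edgeR without the block. Over 7811, 9933 and 5936 shared regions, 0 passed for POLR2, POLR2S5 and POLR2S2, with 174, 288 and 349 at an unadjusted p under 0.05. In simulated counts this test without the block recovered 0% of the planted 2-fold and 4-fold changes. The lack of calls therefore cannot decide whether single regions changed. DESeq2 called 1, 7 and 32 regions higher and 0, 12 and 21 lower at 4% O2, and edgeR with the replicate block 1, 0 and 5 higher and 1, 3 and 6 lower. With the block, POLR2S2 rose at Pde10a, a phosphodiesterase gene, by a log2 ratio of 3.74 ± 0.31 (chromosome 17, 8521801 to 8624400, edgeR adjusted p = 0.0106), with 2635 and 6313 reads against 104 and 257. POLR2S2 was lower at Bcat1, a branched-chain aminotransferase, at -3.92 ± 0.40 (chromosome 6, 145030201 to 145070400, edgeR adjusted p = 0.0177). POLR2S5 was lower at Snd1, a nuclease, at -5.14 ± 0.31 (chromosome 6, 28842201 to 28911400, edgeR adjusted p = 0.0125), with 84 and 43 reads against 1540 and 1728. POLR2 rose at Flrt1 and Macrod1 by 2.23 ± 0.26 (chromosome 19, 7147801 to 7161400, edgeR adjusted p = 0.0278). It was lower at the histone genes H1f2, H2bc3 and H3c3 at -1.99 ± 0.26 (chromosome 13, 23737401 to 23748000, edgeR adjusted p = 0.0391). Island lengths differed at the same regions, and per kb the ratios were 0.01 at Pde10a, -0.82 at Bcat1, 0.33 at Snd1, -0.42 at Flrt1 and -0.47 at H1f2. Without the 20% O2 library of round 2, edgeR called 178 regions higher and 17 lower for POLR2 and 45 and 5 for POLR2S5.

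CTCF was called at the ends of 253 genes in both 4% O2 libraries only and of 25 genes in both 20% O2 libraries only. At 4% O2 the leading genes by rank within the lists included Pomgnt2 (chromosome 9, 121981606 to 121996053, mean percentile 99.6). Tbl3 and Pou5f1, a pluripotency factor, stood at 78.5 and 66.7. At 20% O2 the first were L1td1 (75.6) and Galp, a galanin-like peptide gene (71.5). Among list members, Ccnd1, Mcm7, Fdps, Sod2, Canx and Stx1a were called at 4% O2 only, and no list passed (adjusted p = 1.0 by Fisher's exact test). Crossed pairs of libraries gave 94 and 40 genes, and rounds alone 903 and 165. Without 4% replicate 1 the counts were 668 and 370, without 4% replicate 2 858 and 81, without 20% replicate 1 631 and 161, and without 20% replicate 2 532 and 271.

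POLR2S2 was called at the ends of 302 genes at 4% O2 only and 51 at 20% O2 only, and over the whole gene for 326 and 39. Jak3, a cytokine receptor kinase, led at 4% O2 (chromosome 8, 71676383 to 71690577, mean percentile 98.8), with Agrp, a neuropeptide gene (95.1), Itga10 (92.8) and Gata2, a transcription factor of sympathetic neurons (91.6). At 20% O2 Nppb, a natriuretic peptide gene, led (chromosome 4, 147985786 to 147987205, 99.3), with Nipbl, the cohesin loader (96.6), and Pik3r1 (91.7). Dusp1, Nr4a1 and Mvk were further list members at 4% O2 and Slc7a11 at 20% O2, and no list passed (adjusted p = 1.0 by Fisher's exact test). Crossed pairs gave 109 and 44 genes and the rounds 97 and 466. Leaving out 1 library gave 712 and 288 without 4% replicate 1 and 438 and 180 without 4% replicate 2. It gave 433 and 220 without 20% replicate 1 and 2122 and 170 without 20% replicate 2.

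**Figure D3:**
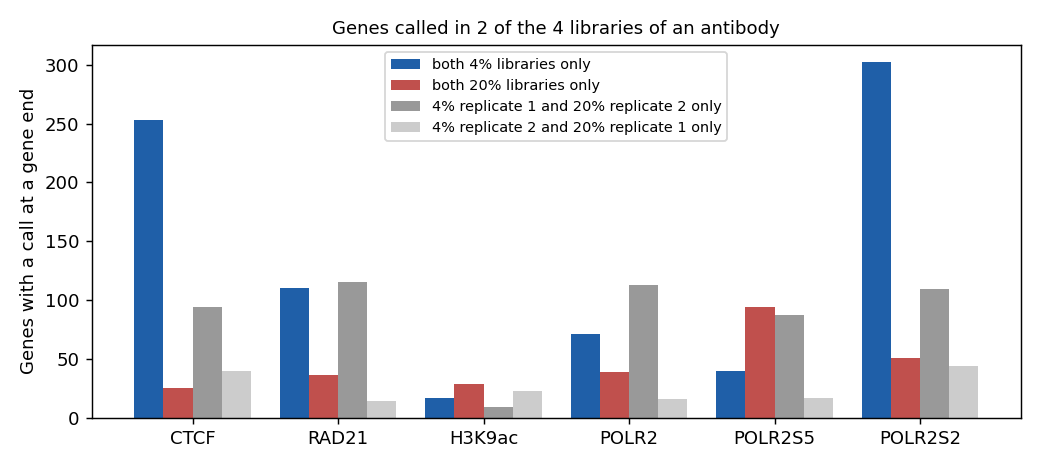
Number of protein-coding genes with a call at a gene end (vertical axis) in exactly 2 of the 4 libraries of each antibody, with blue bars for both 4% O2 libraries, red for both 20% O2 libraries and grey for crossed pairs. CTCF (253 against 25) and POLR2S2 (302 against 51) had more genes at 4% O2 than at 20% O2 or in either crossed pair.

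For RAD21 and POLR2 neither O2 count stood above both crossed pairs, while the 20% O2 count of H3K9ac did. That of POLR2S5 did so only with genes of a shared end counted singly: 23 of its 94 genes were called on the same protocadherin islands. With genes on the same islands counted once it was 68 against 86 in a crossed pair, and over whole genes 55 against 95. RAD21 was called at 110 genes at 4% O2 only, led by Celsr3, a cadherin gene (mean percentile 86.4), and 36 at 20% O2 only, led by Etv3l (65.5), with 115 and 14 in crossed pairs. H3K9ac gave 17 and 29 genes, led by Dusp26, a phosphatase gene (81.0), and Rbmx2 (51.1), with 9 and 23 crossed. POLR2 gave 71 and 39, led by Fbxo42 (99.7) and Aida (96.4), with 113 and 16 crossed; the imprinted gene Nnat was among the 71 (99.0). POLR2S5 gave 40 and 94, led by Cplane1 (99.5) and Mroh3 (95.8), with Hoxc4 and Hoxc5 at 93.9 at 20% O2 and Hspa1b, a heat shock gene, at 77.1 at 4% O2; crossed pairs gave 87 and 17. Leaving out a library turned the direction in several cases: POLR2 gave 99 and 318 and RAD21 119 and 814 without 20% replicate 1. POLR2S5 gave 1292 and 204 without 20% replicate 2, and H3K9ac 201 and 50 without 4% replicate 1 and 182 and 105 without 20% replicate 2. RAD21 also gave 1653 and 58 without 20% replicate 2 and 1042 and 78 without 4% replicate 1. POLR2 gave 3017 and 78 without 20% replicate 2. A level left with 1 library needs a call in that library alone, which raises its count, so a turn toward that level carries no weight.

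Of the genes specific in the same direction for several antibodies, Ucma, Odf3b, Slc13a4 and Prg3 were called at 20% O2 and Sp7, Stim1, Ak4 and Nbl1 at 4% O2. Stim1, a calcium sensor of the endoplasmic reticulum (chromosome 7, 102261514 to 102437319), and Ak4, a mitochondrial adenylate kinase (chromosome 4, 101416478 to 101467771), were called by POLR2S5 and POLR2S2. Their mean percentiles were 64.6 and 64.0. Gm29776 was called by all 3 polymerase forms at 4% O2 only (chromosome 14, 54691045 to 54698976, 77.2).

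Of 274 list tests, 1 passed. Protocadherin cluster genes, which encode neuronal adhesion proteins, were called for POLR2S5 at 20% O2 only at 9 of 26 genes (odds ratio 83.14, Fisher's exact p = 7.6e-14, adjusted p = 2.1e-11). The 9 genes, among them Pcdhga1, Pcdhgb1, Pcdhgc4 and Pcdhgc5, share 1 gene end, and the call rested on 1 island in each 20% O2 library. These islands lay on chromosome 18 at 37839001 to 37841400 in round 1 and 37841201 to 37845200 in round 2, at percentiles 13.5 and 11.5 of their lists. Over whole genes no protocadherin gene was called for POLR2S5 at 20% O2 only, so the call held at gene ends alone.

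Away from single genes, regions specific to 4% O2 outnumbered those specific to 20% O2 for CTCF (2126 against 959), H3K9ac (1721 and 1071), POLR2 (389 and 123), POLR2S5 (517 and 415) and POLR2S2 (1285 and 291), but not RAD21 (962 and 985). The direction turned for H3K9ac with regions merged within 1 kb (512 and 573) and with equal lists (1094 and 1365), and for POLR2S5 with the better scoring 50% of each list (189 and 206). Without 20% replicate 1 it turned for CTCF (6055 and 6904), H3K9ac (3459 and 9874), POLR2 (424 and 3130), POLR2S5 (667 and 2635) and POLR2S2 (1547 and 1686). Without 20% replicate 2 it turned for CTCF (3821 and 19544) and H3K9ac (4992 and 7099). RAD21 turned without 4% replicate 1 (20736 and 1991), 4% replicate 2 (3092 and 1897) and 20% replicate 2 (9553 and 1566). A level left with 1 library needs a call in that library alone, which raises its count. A turn toward that level therefore carries no weight. Summed over levels, O2-specific regions numbered 3085 for CTCF, 1947 for RAD21, 2792 for H3K9ac, 512 for POLR2, 932 for POLR2S5 and 1576 for POLR2S2. Crossed pairs gave 2567, 1938, 1722, 985, 947 and 451, and rounds 31684, 11907, 12205, 2059, 2022 and 1707. With equal lists the O2-specific totals were 1073, 1677, 2459, 514, 1084 and 1499, in the same order of antibodies. Crossed pairs then gave 1059, 772, 1559, 502, 545 and 382, so the CTCF excess over them was nearly lost. Of the CTCF regions, 22.8% of those at 4% O2 only lay at a gene end against 6.3% at 20% O2 only (odds ratio 4.43, Fisher's exact p = 3.4e-33), and of the RAD21 regions 18.3% against 4.7% (4.57, p = 3.6e-22). POLR2 went the other way, with 13.6% against 60.2% (odds ratio 0.1, Fisher's exact p = 4.8e-23), as did POLR2S5, with 8.5% against 37.8% (0.15, p = 8.1e-28). For these forms regions at 4% O2 only were narrower, with median widths of 3400 against 6400 bp and 3200 against 7200 bp. The 20% O2 library of round 1 had the highest share of island centres at gene ends, 42.3% for POLR2 and 24.0% for POLR2S5. Width and that library cannot be told apart from O2 here. H3K9ac gave 8.9% against 6.5% (odds ratio 1.41, Fisher's exact p = 0.026) and POLR2S2 32% against 25.8% (1.35, p = 0.041). Regions are not independent replicates. Leading regions away from gene ends included CTCF at 4% O2 inside Micos10 (chromosome 4, 139104607 to 139104831, mean percentile 66.6). POLR2S2 led inside Rbms3 at 4% O2 (chromosome 9, 117205001 to 117265200, 90.0) and inside Ptk2 at 20% O2 (chromosome 15, 73218401 to 73373600, 90.4).

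RAD21 peaks overlapped CTCF peaks at 82.0% and 67.9% at 4% O2 and 96.7% and 67.8% at 20% O2 in rounds 1 and 2 (75.0 ± 10% against 82.2 ± 20.4%, SD, n = 2, exact permutation p = 1.0). CTCF peaks overlapped RAD21 peaks at 28.2% and 54.0% against 21.3% and 61.4%. H3K9ac peaks at gene ends overlapped POLR2S2 islands at 79.0% and 86.5% at 4% O2 and 38.2% and 78.2% at 20% O2, differences of 40.8 and 8.3 points in the rounds (82.7 ± 5.3% against 58.2 ± 28.3%, SD, n = 2, exact permutation p = 0.333). For POLR2 the overlaps were 93.4% and 93.5% against 64.2% and 95.1%, and for POLR2S5 95.3% and 94.5% against 78.8% and 96.2%. POLR2 islands overlapped H3K9ac peaks at 90.8% and 92.5% against 81.3% and 87.9% (exact permutation p = 0.333).

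Nos1, the neuronal nitric oxide synthase gene that the cells are named for, had no H3K9ac or RAD21 peak at its ends in any library. POLR2S2 islands lay at its ends in all 4 libraries, with the strongest at percentiles 65.0 and 87.7 at 4% O2 and 70.9 and 94.9 at 20% O2. POLR2S5 islands lay there at 49.0 in 4% O2 replicate 1 and at 10.5 and 68.4 at 20% O2, and POLR2 in 20% O2 replicate 2 alone (22.7). CTCF peaks lay at its ends in 4% O2 replicate 2 alone (percentile 15). CTCF had 20 and 29 peaks over the gene at 4% O2 and 27 and 15 at 20% O2, and RAD21 5 and 14 against 4 and 8.

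Peak centres lay at gene ends for 10.2% and 12.9% of CTCF peaks at 4% O2 and 8.8% and 11.7% at 20% O2, in rounds 1 and 2. For RAD21 these shares were 12.5% and 13.9% against 10.9% and 12.5%, and for H3K9ac 23.4% and 19.3% against 25.2% and 20.8%. POLR2 had 24.6% and 21.5% against 42.3% and 24.0%, POLR2S5 17.2% and 16.1% against 24.0% and 17.7%, and POLR2S2 16.3% and 16.2% against 15.2% and 22.1%.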

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

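The tests of list length and island number, of the random lists, of the separate rounds, of the interval of the H3K9ac share and of neighbouring genes were chosen after the results they bear on were seen.

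The peak number moved in opposite directions in the rounds for 5 antibodies; these differences between rounds were not tested. The ratio of 4% to 20% O2 was 0.98 in round 1 and 1.12 in round 2 for CTCF, 1.45 and 0.97 for RAD21, 1.78 and 0.8 for POLR2, 1.07 and 0.86 for POLR2S5, and 1.07 and 0.93 for POLR2S2. Signal on the mitochondrial chromosome, outside the comparisons, was listed as 4 and 3 CTCF peaks in replicate 2 at 4% and 20% O2, as 2 RAD21 peaks in 4% O2 replicate 1 and as 8 and 20 RAD21 peaks in replicate 2 at 4% and 20% O2. Islands there held 23234 and 10378 POLR2 reads in 4% O2 replicates 1 and 2 and 9780 in 20% O2 replicate 2, and 4475 POLR2S5 and 6419 POLR2S2 reads in 20% O2 replicate 2.

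CTCF was called at the ends of 253 genes at 4% O2 only and 25 at 20% O2 only, which longer lists at 4% O2 do not account for, since lists of equal length gave a ratio of 6.74. Cohesin joining CTCF at most of these regions is argued against by RAD21 at 8.0% and 36.3% of them in the 4% O2 libraries, below the 50% set beforehand, but these shares stood above the 1.6% and 21.0% at 20% O2, so joining at a part of them stays open. Signal drawn to acetylated chromatin stays open too: 76.7% of the regions overlapped an H3K9ac peak, against 35% of those at 20% O2 only. This share missed the 80% set beforehand, but its 95% interval, 72.7% to 80.2% with regions taken as independent, narrowly held that limit, and it missed a margin of 20 points over regions called in all 4 libraries, which could hardly be reached from their 77.4%. Weak signal near the calling threshold stays open, since the regions had a median percentile of 28.0 against 81.1 for regions called in all 4 libraries, as does a response of CTCF binding to O2.

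POLR2S2 was called at 302 gene ends at 4% O2 only and 51 at 20% O2 only. Without the 20% O2 library of round 1, which had the fewest island reads, the ratio was 1.97, so that library was not the whole cause at gene ends, though the ratio with all libraries was 5.92. Over regions the direction turned without it (1547 and 1686, against 1285 and 291). A region at 20% O2 only then needs just 1 library, which raises that count, so the turn cannot decide the share of that library in the pattern. Its share stays open. A larger number of islands at 4% O2 is argued against by the ratio of 0.93 in round 2. The larger read totals and covered lengths of the 4% O2 libraries stay open, since sequencing depth is not given, and so does a response of elongating polymerase to O2.

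HIF targets and glycolysis regions had more polymerase reads at 4% O2. Size and read level of the list did not account for its medians, which lay at a lowest percentile of 100 among random lists. Such lists draw regions as if independent from the same libraries. They cannot exclude chance differences between libraries or shared variation of the list members. One round alone did not carry the higher reads of the list, since the lowest median within a round was 0.26. Nor did neighbouring genes, since over regions with 1 gene the lowest percentile was 99.48. Island length stays open for POLR2, where reads per kb placed the list at percentile 6.55. For POLR2S5 and POLR2S2 the list medians fell to -0.05 and 0.12 per kb, with all shared regions at -0.3 and -0.37. Island length may therefore account for a part of the gain in these forms, though the list stayed at percentiles 99.97 and 100. With an estimated correlation no camera call held (unadjusted camera p = 0.056, 0.052 and 0.053). That correlation was estimated from 2 libraries per level, so the miss cannot decide for or against a response. A response of these genes to O2 may be named only as a hypothesis.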

How the results depend on the processing

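The similarity across rounds, the random lists of gene-end regions and the counting of shared gene ends once were chosen after seeing the data. Of the alternatives, 167 left a result on the same side of its threshold, within 1.5 times for counts or within the spread between replicates or rounds for other values, and 158 did not. Of the latter, 26 and 24 came from leaving out 4% replicates 1 and 2, and 18 and 28 from leaving out 20% replicates 1 and 2. A level left with 1 library needs only that library, which raises region and gene-end counts. Causes were otherwise not tested.

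The similarity difference reversed to 0.015 across rounds and passed at -0.071 with the replicate block. The replicate block also gave 1 region higher and 1 lower for POLR2, 3 lower for POLR2S5, and 5 higher and 6 lower for POLR2S2, and ratios of peak number in round 1 alone of 1.45 for RAD21 and 1.11 for H3K9ac (both 1.1 pooled), 1.78 for POLR2 (1.12), 0.98 for CTCF (1.03) and 1.07 for POLR2S5 (0.96). In round 2 alone those of RAD21 and POLR2 crossed 1, at 0.97 and 0.8. DESeq2 gave 1 region higher for POLR2, 7 higher and 12 lower for POLR2S5, and 32 higher and 21 lower for POLR2S2.

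With the better scoring 50% of each list, regions at 4% and 20% O2 only numbered 647 and 89 for CTCF, 92 and 252 for RAD21, 1039 and 513 for H3K9ac and 189 and 206 for POLR2S5, where the direction turned, and those at 4% O2 133 for POLR2 and 637 for POLR2S2. Gene ends became 30 and 9 for RAD21, 38 and 24 for H3K9ac, where the direction turned, 65 at 4% O2 for POLR2S5, and 62 and 93 at 20% O2 for POLR2 and POLR2S2. RAD21 peaks with CTCF reached 90.3% at 4% O2 and 91.7% at 20% O2, and with equal lists 94.8% and 96.6%. In round 1 the shares with equal lists were 94.2% at 4% O2 and 95.1% at 20% O2. Equal lists gave 647 and 426 CTCF regions, 1094 and 1365 H3K9ac regions, where the direction turned, 155 CTCF gene ends at 4% O2, 56 H3K9ac gene ends at 20% O2, and 133 and 80 POLR2 gene ends. Merging within 1 kb gave 657 and 133 CTCF, 565 RAD21 (4% O2), and 512 and 573 H3K9ac regions, where the direction turned. Genes on the same peaks counted once left all gene-end counts within 1.5 times, such as 239 and 25 for CTCF, 292 and 50 for POLR2S2 and 40 and 68 for POLR2S5. Windows of 2.5 kb gave 159 and 15 CTCF gene ends. Whole genes gave 95 and 8 for CTCF, 11 and 48 for H3K9ac, 35 and 55 for POLR2S5, and 93 and 138 for RAD21, where the direction turned.

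Against random lists of gene-end regions, CTCF rank differences fell inside the middle of the lists for HIF targets (percentile 63.26), nitric oxide signalling (72.85), neuronal structure (61.16), oxidative phosphorylation (89.38), cholesterol synthesis (92.79) and histone demethylases (85.52). So did RAD21 for immediate early genes (91.53), cholesterol synthesis (90.54) and ribosomal proteins (91.3), while POLR2S2 at neuroblast genes moved past the limit (2.32).

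Leaving out each library in turn gave these lowest and highest counts, at 4% and then 20% O2. Regions: CTCF 3821 to 18052 and 1634 to 19544, RAD21 1033 to 20736 and 1566 to 19751, H3K9ac 3459 to 19622 and 2053 to 9874, POLR2 424 to 6435 and 265 to 3130, POLR2S5 667 to 4842 and 705 to 3074, POLR2S2 1547 to 3917 and 479 to 2110. Gene ends: CTCF 532 to 858 and 81 to 370, RAD21 119 to 1653 and 58 to 814, H3K9ac 40 to 201 and 50 to 301, POLR2 99 to 3017 and 78 to 318, POLR2S5 70 to 1292 and 204 to 298, POLR2S2 433 to 2122 and 170 to 288. Shared regions with more and with fewer reads at 4% O2: POLR2 0 to 178 and 0 to 17, POLR2S5 0 to 45 and 0 to 5, POLR2S2 0 to 0 and 0 to 0. With a library left out, the lone library of a level was assumed to vary like the others, and a region needs only that library, which raises such counts. The CTCF motif was not run.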

Other observations

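The histone genes were chosen as a set after their polymerase reads had been seen in POLR2; their test in POLR2S5 and POLR2S2 was written before the values of the set were seen there, though the leading regions of both had been viewed and held no histone gene.

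Replication-dependent histone genes carried fewer polymerase reads at 4% O2. All 20 regions of the set for POLR2, all 20 for POLR2S5 and all 13 for POLR2S2 were lower in both rounds, with median log2 ratios of -1.11, -1.2 and -1.27. Per kb of island the medians were -0.98, -0.89 and -1.04, where those of all shared regions were -0.48, -0.30 and -0.37, so the set stood closer to other regions on that scale. The region of H2ac11, H2bc11 and H4c9 on chromosome 13, 22039201 to 22044600, had a POLR2 ratio of -1.79 ± 0.51 (SE). The region of H1f5 and H3c11 on the same chromosome had -1.46 ± 0.49 in POLR2, -1.55 ± 0.55 in POLR2S5 and -1.73 ± 0.77 in POLR2S2. The set was picked from POLR2, so tests in that form carry no weight. For POLR2S5 and POLR2S2, adjusted over the list alone, 0 regions passed edgeR, and 17 and 0 with the replicate block. Camera gave p = 3.5e-14 and 1.1e-07, and p = 0.2 and 0.22 with an estimated correlation.

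A hypothesis is that polymerase occupancy of histone genes is lower at 4% O2 in all 3 polymerase forms. The median of the set lay at percentile 0.0 of random lists for POLR2S5 and POLR2S2, which the hypothesis requires. These are forms of the same polymerase, sequenced in the same rounds as POLR2, from which the set was picked. The result is therefore not an independent test. Within round 2 alone the POLR2S2 median lay at percentile 2.73, short of the limit of 2.5 set for the test. The share of cells in S phase was not measured here.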
